A study of Mus musculus with 74 samples.

How the data were processed

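Of 74 samples of mouse quadriceps, 57 have values in 7 tables, in 62 columns, and 17 have no column of their own. Groups were taken from the labels: 5 knockout, 4 Cre-negative and 4 oil-treated Cre-positive RNA libraries, 4 knockout and 4 control RiboTag animals with footprint and mRNA libraries each, 3 knockout and 3 Cre-negative H3K27ac libraries in each of 3 series, and 5 FX1 and 5 DMSO nascent RNA libraries. The 8 chronic RNA libraries, the input libraries and the single wild-type H3K27ac library were not used here.

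Per the submitters' processing notes, reads were aligned to mm10 with STAR 2.4.0 or Bowtie 1.2 and processed with HOMER (no version named) and DESeq2 1.14.1; the notes do not say which tool made which file. Per the file headers, the poly(A) and nascent RNA tables hold log2 values that the authors made with HOMER from tags in exons or in gene bodies and then transformed with a method that is not named. Per the file headers, the RiboTag tables hold deposited counts of tags in genes with at most 5 tags per position. Genes with more than 1 tag per exon base in any library, a density below the cap itself, were taken here as near it. These 1167 genes held 36.8% to 45.1% of the counts of a library. Per the file headers, the H3K27ac tables hold a deposited signal, tags per region scaled to 10000000 tags per library, with the acute and chronic series counted in the same merged regions and the third series in 1000 bp windows on BCL6 peaks. The BCL6 peak list gives the authors' peak score, whose scale is not named, for 1 library. The authors' deposited tables also give a p-value (p_value), an adjusted p-value and a log2 fold change per gene, used only for a comparison of calls.

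Counts were tested with edgeR 4.0.16 (quasi-likelihood, TMM, filterByExpr with a minimum count of 10), and translation efficiency as the interaction of genotype and library type in the 16 RiboTag libraries. Log2 values were tested with limma 3.58.1 with a trended variance, and H3K27ac signal in the same way after log2 of the signal plus 1. Genes and regions were called at a Benjamini-Hochberg adjusted p below 0.05 within each comparison. Gene lists, 31 in all and 30 with members in the tables, were written down from general knowledge before the data were examined, and were tested with camera at a preset correlation of 0.01, with camera at the estimated correlation and with fry. Lists cover muscle fibre types, metabolism, growth, stress and immune pathways, and markers of cells other than muscle fibres. Overlap of regions and peaks used GenomicRanges 1.54.1 (at least 1 bp), a gene was bound if a peak lay within 1000 bp of its start, and bound shares were compared by Fisher's exact test. Other tools were R 4.3.3, DESeq2 1.42.0, the data.table package (1.17.8), Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

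The genes named are 9 fixed genes (Bcl6, Socs2, Cish, Igf1, Eif4ebp1, Fbxo32, Trim63, Mstn and Ddit4), the 6 raised and 6 lowered called genes with the largest fold and with a mean of at least 5 CPM and groups without overlap, and up to 3 called members with the smallest p of each list. Regions named are the 5 raised and 5 lowered called regions with the largest fold and those of the fixed genes, and peaks named are the 10 with the highest score and those of named regions or genes. Samples, comparisons, lists, the main tests and most alternatives were chosen before the data were examined. Quantile normalization, a common variance prior, leaving out genes near the position cap, edgeR with TMM on recovered reads, a pseudocount of 5 and a replicate block in the list tests were chosen after seeing the data. Recovered reads are the signal scaled back by the library total and rounded to whole tags.

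The fits were tested on simulated data with 200 changed genes or regions in each comparison. At log2 changes of 0.5, 1 and 2, 17.9%, 77.6% and 95.5% were recovered in RiboTag mRNA (14476 genes run), 28.4%, 79.1% and 98.5% in footprints (12979 genes run), and 2.99%, 49.3% and 87.9% in translation efficiency (14935 genes run). Recovery was 100% at each size against Cre-negative muscle (13732 genes run) and against oil (13754 genes run), and 23.9%, 76.1% and 98.5% in nascent RNA (15683 genes run). For these log2 values the changes were added after the authors' transform, so recovery of changes made before it was not tested. For H3K27ac recovery was 1.49%, 22.4% and 77.3% in the acute series (67976 regions run), 0%, 22.4% and 60.6% in the chronic series (65836 regions run) and 31.3%, 80.6% and 95.5% in windows (9167 regions run). Unchanged features made up 1.47% to 7.97% of the calls. In a test of the lists, 28 glycolysis genes shifted by 0.039 were called (camera adjusted p = 6.6e-10) and 0 other lists were. Genes were simulated independently of one another, so this does not test whether correlated genes give false list calls.

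Library depth ranges are given at the start of the report. The whole-gene tables do not separate exons, so the deletion of the floxed exons could not be measured.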

Results

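Mouse quadriceps (C57BL/6) was profiled by RNA sequencing, ribosome footprint sequencing, nascent RNA sequencing and chromatin immunoprecipitation, and 57 of the 74 samples have values in the tables used here. Poly(A) RNA was measured in 5 tamoxifen-treated knockouts (AEC-Esr Cre-positive, Bcl6 floxed), 4 tamoxifen-treated Cre-negative Bcl6 floxed mice and 4 Cre-positive floxed mice given oil. These libraries held 6703586 to 7623960 tags. RiboTag mice carry an HA-tagged ribosomal protein in cells with Cre activity, and HA beads pull those ribosomes down with the RNA they protect. Footprints and poly(A) RNA were measured in 4 RiboTag knockouts and 4 Cre-positive RiboTag controls, all given tamoxifen. The labels call the latter poly(A) RNA but list the anti-HA antibody for it as well, so whether it came from whole muscle or from the pull-down is open. Counts in genes ran from 3248807 to 4370468 per footprint library and from 6499561 to 13045854 per mRNA library. Acetylation of histone H3 at lysine 27 (H3K27ac, a mark of active promoters and enhancers) was measured in 3 knockouts and 3 Cre-negative controls in each of 3 series. These were an acute series (11772723 to 20773905 tags), a chronic series (7794885 to 23016334 tags) and animals with RNA sequencing (15007526 to 22722409 tags). Nascent RNA was measured in 5 wild-type mice given FX1, an inhibitor of BCL6, and 5 given the solvent DMSO (13947139 to 32670917 tags). BCL6 binding came from 1 library without replicate. The 8 chronic RNA libraries, the inputs and a wild-type H3K27ac library were not used here.

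Bcl6 transcript levels differed little between knockout and control muscle, whereas its footprints were lower. In poly(A) RNA, Bcl6 stood at 10.34 ± 0.088 (SD, n = 4) in Cre-negative and 10.11 ± 0.12 (SD, n = 5) in knockout muscle in the authors' transformed log2 values. It fell by 0.23 (SE 0.057, adjusted p = 0.0134). The knockout samples P1895, P1896, P1900, P1907 and P1911 stood at 10.09, 10.22, 9.99, 10.25 and 9.98. The Cre-negative samples P1898, P1899, P1906 and P1909 stood at 10.21, 10.41, 10.36 and 10.38. Against oil-treated Cre-positive muscle, where samples P1897, P1904, P1905 and P1910 stood at 10.43, 10.31, 10.52 and 10.52, Bcl6 fell by 0.31 (SE 0.061, adjusted p = 0.00264). RiboTag Bcl6 mRNA was 208.8 ± 95.7 CPM (counts scaled to library size; SD, n = 4) in controls, from 125.3 to 317.9, and 229 ± 39.8 (SD, n = 4) in knockouts, from 184.2 to 273.8. This difference did not pass (log2 change 0.14, adjusted p = 0.840). Bcl6 footprints fell by 1.12 on the log2 scale (SE 0.195, adjusted p = 0.00201), from 193.7 ± 57.9 CPM (SD, n = 4; 118.6 to 257.4) to 91.2 ± 16.2 CPM (SD, n = 4; 70.7 to 107.7). In nascent RNA Bcl6 stood at 10.34 ± 0.23 (SD, n = 5; 10.03 to 10.67) with DMSO and 10.74 ± 0.53 (SD, n = 5; 9.86 to 11.28) with FX1 (log2 change 0.40, adjusted p = 0.233). It passed without FX1 sample 3. The tables give whole-gene values, so reads from the floxed exons were not separated. The Bcl6 call against Cre-negative muscle was lost with quantile normalization.

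**Figure D1:**
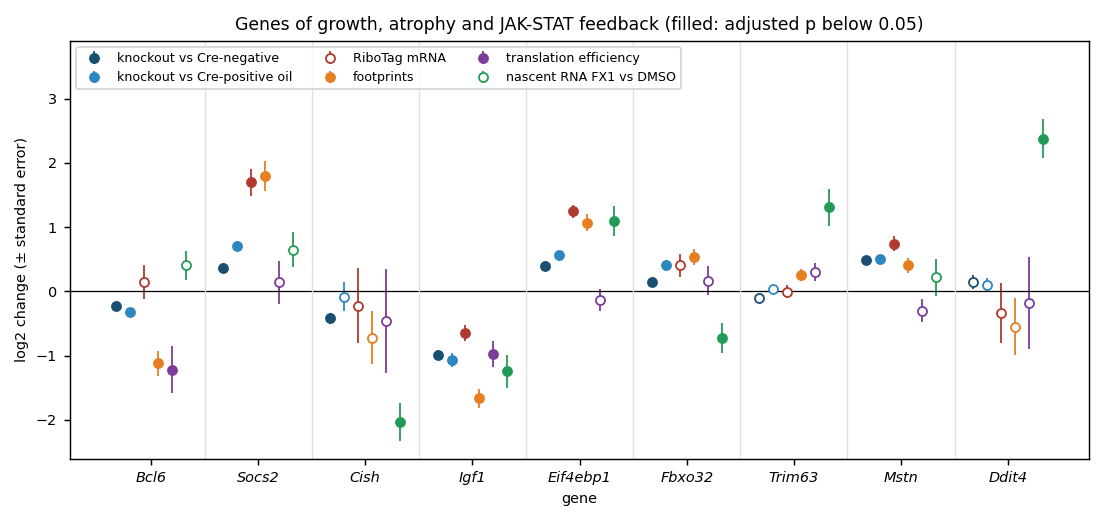
Log2 change (vertical axis, with its standard error) of 9 genes fixed in advance (horizontal axis) in 6 comparisons, with filled points for adjusted p below 0.05. Igf1 is below 0 in all 6, from -0.65 to -1.66, and Socs2 reaches 1.69 in RiboTag mRNA and 1.79 in footprints. Sizes from the authors' transformed log2 values and from RiboTag counts are not comparable.

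The comparison of knockout with Cre-negative quadriceps, both given tamoxifen, asks which muscle transcripts change after loss of Bcl6. Igf1, the growth factor that stimulates muscle protein synthesis, fell by 0.98 on the log2 scale (SE 0.068, adjusted p = 1.12e-06), from 9.94 ± 0.18 (SD, n = 4) to 8.96 ± 0.089 (SD, n = 5). Mstn, which encodes the growth inhibitor myostatin, rose by 0.49 (SE 0.030, adjusted p = 3.04e-07). Eif4ebp1, a repressor of cap-dependent translation, rose by 0.40 (SE 0.036, adjusted p = 1.16e-05). Among feedback inhibitors of cytokine signalling, Socs2 rose by 0.36 (adjusted p = 0.00388), with knockout P1900 far above the other knockouts, and Cish fell by 0.42 (adjusted p = 0.00573). In all, 2096 of 13732 genes passed in limma, 830 raised and 1266 lowered, and with quantile normalization 911 were raised and 976 lowered. Of the genes tested, 15.2% had groups without overlap where chance gives 1.59%.

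The method behind the log2 values is not named, and whether it shrinks genes with few tags is open, so sizes and their order hold for these values only. The largest rises among expressed genes were those of Chrna9, a nicotinic acetylcholine receptor subunit (1.65), the estrogen receptor gene Esr1 (1.34, with Cre-negative sample P1898 far below the other controls), the imprinted noncoding RNA Rian (1.11), Wnt4 (0.91), the deubiquitinase gene Usp46 (0.89) and Atp1b4 (0.86). In the authors' fold changes against Cre-negative muscle Esr1 (1.71) stands above Chrna9 (1.32). Esr1 did not pass against Cre-positive oil controls (log2 change 0.016, adjusted p = 0.786). After Igf1, the largest falls were those of Gprc5c (-0.97), the myosin phosphatase subunit Ppp1r12b (-0.84), the potassium channel subunit Kcng4 (-0.79), Tnfaip2 (-0.78) and the spermine oxidase Smox (-0.77). The atrophy ubiquitin ligase Fbxo32 rose by 0.15 (adjusted p = 0.0259), with Cre-negative sample P1909 far above the other controls and a call that was lost with any of 6 libraries left out. Trim63, another atrophy ligase (log2 change -0.10), and the mTORC1 inhibitor Ddit4 (0.14) did not pass. Trim63 passed without knockout P1911 and Ddit4 without Cre-negative P1898.

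Fibre-type genes moved in opposite directions. Calls of whole lists need care, since other splits of the libraries called as many lists as the real split in 38 of 100 splits here, 39 of 100 against oil, 24 of 35 in RiboTag mRNA and 65 of 100 in nascent RNA, the real split included. Of 19 genes of the fast-fibre sarcomere and calcium handling, 9 fell and 1 rose (12 and 1 adjusted over the list alone; camera adjusted p = 3.8e-05), among them Casq1 (-0.21), Myl1 (-0.24) and Myoz3 (-0.21). Of 16 slow-fibre genes, 5 rose and none fell (9 and 1 adjusted over the list alone; adjusted p = 9.0e-05), among them Casq2 (0.42), Myl2 (0.28) and Myoz2 (0.23). Both lists had an adjusted p = 0.745 with an estimated correlation. Of 28 glycolysis and glycogen genes 15 fell and 2 rose (19 and 3 adjusted over the list alone; adjusted p = 8.8e-07, and adjusted p = 0.685 with an estimated correlation). The phosphorylase kinase subunit Phka1 (-0.34) fell, whereas the gluconeogenic bisphosphatase Fbp2 rose (0.36). Of 24 lipid synthesis genes 5 fell (5 adjusted over the list alone), including Scd2 (-0.33) and Gpam (-0.18; adjusted p = 0.0014, and adjusted p = 0.685 with an estimated correlation).

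Of 29 matrix and TGF-beta genes, 8 fell and 2 rose (16 and 2 adjusted over the list alone; adjusted p = 0.00078), with Col5a1 (-0.29) and Col6a3 (-0.33) lower. The list had an adjusted p = 0.870 with an estimated correlation. Of 95 markers of 9 other cell types 2 rose and 3 fell, and the medians of tendon and fibroblast markers were -0.08 and -0.024. Of 23 denervation and regeneration genes, 8 rose and none fell (8 and 1 adjusted over the list alone; adjusted p = 0.0042, and adjusted p = 0.685 with an estimated correlation), among them the acetylcholine receptor subunit Chrna1 (0.63), the calcium pump inhibitor sarcolipin (Sln, 0.85) and Gadd45a (0.36). Of 72 oxidative phosphorylation genes 6 fell (4 adjusted over the list alone; adjusted p = 0.0037). Of 80 cytosolic ribosomal protein genes 1 rose (0 adjusted over the list alone; adjusted p = 0.013). Both had an adjusted p = 0.995 with an estimated correlation. The ribosomal protein call was lost without knockout P1900 (adjusted p = 0.134) or Cre-negative P1906 (adjusted p = 0.441). Atp5a1 (-0.10) turned to 0.021 with quantile normalization. Within growth hormone and IGF1 signalling 6 of 26 genes rose and 8 fell, without a group call (7 and 9 adjusted over the list alone; adjusted p = 0.220). Akt1 rose by 0.65 and Igfbp5 fell by 0.52.

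The same knockout libraries were set against Cre-positive floxed muscle given oil, a control that carries the Cre transgene but differs in treatment as well as genotype. Igf1 fell by 1.07 (SE 0.106, adjusted p = 1.33e-05). Socs2 rose by 0.71 (adjusted p = 2.19e-05, knockout P1900 again far above the rest), Eif4ebp1 by 0.57 (adjusted p = 2.19e-07), Mstn by 0.50 (adjusted p = 1.06e-07) and Fbxo32 by 0.42 (adjusted p = 0.00119). Cish (-0.08), Trim63 (0.03) and Ddit4 (0.10, with oil sample P1910 far above the other controls) did not pass. Cish passed without oil sample P1905. Of 13754 genes 3216 passed in limma, 1360 raised and 1856 lowered. Of the tested genes 21.1% had groups without overlap where chance gives 1.59%. By these log2 values the adhesion molecule gene Flrt1 rose most, from 7.47 ± 0.105 (SD, n = 4) to 10.09 ± 0.054 (SD, n = 5). Against Cre-negative muscle Flrt1 did not pass (log2 change 0.12, adjusted p = 0.0535), and with FX1 its nascent RNA fell by 0.96 (adjusted p = 0.00135). In the authors' fold changes against oil Chrna9 (4.09) stands above Flrt1 (3.74). Next by the log2 values came Chrna9 (1.95), Rian (1.33), Usp46 (1.136), Sln (1.09) and the imprinted noncoding RNA Meg3 (0.97). Before Igf1, the largest falls were those of Ppp1r12b (-1.39), Smox (-1.32), Kcng4 (-1.26), Rasd2 (-1.13) and Dupd1 (-1.09).

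Slow-fibre genes rose, with 12 of 16 raised and none lowered (15 and 0 adjusted over the list alone; adjusted p = 3.6e-09, and adjusted p = 0.252 with an estimated correlation), among them Casq2 (0.75), Myl2 (0.40) and Myoz2 (0.35). Of 28 glycolysis and glycogen genes 16 fell and 2 rose (18 and 4 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.664 with an estimated correlation), again with Phka1 (-0.45) lower and Fbp2 (0.71) higher. Of 24 lipid synthesis genes 10 fell (10 adjusted over the list alone; adjusted p = 1.5e-05, and adjusted p = 0.252 with an estimated correlation), including the fatty acid synthase gene Fasn (-0.91), Scd2 (-0.58) and the sterol regulator Srebf1 (-0.21). Of 35 interferon and NF-kB genes 17 rose and 1 fell (18 and 2 adjusted over the list alone; adjusted p = 0.00027, and adjusted p = 0.252 with an estimated correlation), with Ifit1 at 0.26, Irf7 at 0.23 and Ifit3 at 0.18. Of 80 ribosomal protein genes 15 rose and none fell (15 and 0 adjusted over the list alone; median 0.05, adjusted p = 5.2e-07, and adjusted p = 0.747 with an estimated correlation), among them Rpl22 and Rpl27a, both at 0.14. Of 8 erythroid markers 7 rose and 1 fell (7 and 1 adjusted over the list alone; median 0.11, adjusted p = 0.0057, and adjusted p = 0.664 with an estimated correlation), including Alas2 (0.21). Against Cre-negative muscle neither the interferon and NF-kB list nor the erythroid list was called. Over 95 markers of other cell types 14 rose and 8 fell. Of 23 denervation genes 9 rose and 4 fell (11 and 4 adjusted over the list alone; adjusted p = 0.022, and adjusted p = 0.747 with an estimated correlation), with Chrna1 at 0.64. Of 72 oxidative phosphorylation genes 10 fell (9 adjusted over the list alone; adjusted p = 0.041, and adjusted p = 0.859 with an estimated correlation). Without oil sample P1897 the denervation call was lost (adjusted p = 0.0548). The oxidative phosphorylation call was lost without any of 5 libraries, with adjusted p = 0.221 without oil sample P1910.

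Across 13681 genes the changes against both controls had a Pearson correlation of 0.859 (genes are not independent replicates). Because both share the 5 knockouts, simulated data without any effect gave a mean of 0.40 and a highest value of 0.845. Splitting the knockouts between the controls in 20 ways gave 0.749 to 0.801. Raised in both were 621 genes and lowered in both 1070, and the overlap expected without an effect was not computed.

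RiboTag mRNA offers a comparison in separate animals in which both groups carry Cre and received tamoxifen. Chrna9 mRNA went from 0.556 ± 0.425 CPM (SD, n = 4) in controls to 32.1 ± 15.01 CPM (SD, n = 4) in knockouts (adjusted p = 1.83e-05), with knockout mKO_11688 far above the others. The transporter gene Spns3 went from 0.924 to 39.5 CPM, the transcriptional coregulator Cited1 from 1.44 to 49.7, the imprinted gene Rtl1 from 1.137 to 21.2, Acoxl from 0.495 to 10.8 and the vitamin D receptor gene Vdr from 0.553 to 9.91. Eif4ebp1 rose by 1.25 (SE 0.102, adjusted p = 3.51e-05), Socs2 by 1.69 (SE 0.211, adjusted p = 8.09e-04) and Mstn by 0.74 (SE 0.122, adjusted p = 0.00463). Igf1 fell by 0.65 (SE 0.122, adjusted p = 0.0104), with knockout mKO_11688 far above the other knockouts. The largest falls were those of Hmga2-ps1 (-3.42), the T-cell costimulator gene Cd28 (-2.90), Smox (-2.76), the mitochondrial gene Gdap1 (-2.45), Kcng4 (-2.23) and the galanin receptor gene Galr2 (-2.20). Fbxo32 (0.41, adjusted p = 0.259), Cish (-0.22), Ddit4 (-0.34) and Trim63 (-0.0039) did not pass. In edgeR 609 of 14476 genes passed, 283 raised and 326 lowered. Of the tested genes 11.3% had groups without overlap where chance gives 2.86%.

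Of 19 immediate early genes 6 rose and none fell in RiboTag mRNA (14 and 0 adjusted over the list alone; median 0.69, adjusted p = 3.1e-08, and adjusted p = 0.239 with an estimated correlation), among them the transcription factor genes Fos (2.45), Egr3 (2.20) and Fosb (1.99). That list was not called in the comparison of knockout with Cre-negative muscle. Of 16 slow-fibre genes 3 rose (10 raised and 1 lowered adjusted over the list alone; adjusted p = 1.2e-05, and adjusted p = 0.830 with an estimated correlation), namely Casq2 (1.44), Tnni1 (0.67) and Myoz2 (0.39). Of 28 glycolysis and glycogen genes 4 fell and 1 rose (5 and 1 adjusted over the list alone; adjusted p = 1.1e-05, and adjusted p = 0.830 with an estimated correlation), with Gapdh (-1.06) and Phka1 (-0.89) lower and Fbp2 (1.29) higher. Denervation genes included raised Sln (4.03), the embryonic myosin gene Myh3 (1.55) and Chrna1 (0.67), 5 raised and 1 lowered of 23 (8 and 3 adjusted over the list alone; adjusted p = 0.011, and adjusted p = 0.830 with an estimated correlation). Group shifts with few called members were found for oxidative phosphorylation (0 of 72, median -0.18, adjusted p = 3.2e-07) and fast-fibre genes (1 of 19 lowered, 2 adjusted over the list alone, adjusted p = 0.0028). They were also found for ribosomal proteins (0 of 76, median 0.12, adjusted p = 0.0037) and fatty acid oxidation (1 of 35 raised, Acot1 at 1.52, median -0.14, adjusted p = 0.038). For these 4 the values ran from adjusted p = 0.953 to adjusted p = 0.966 with an estimated correlation. Tendon markers moved as well, 1 of 9 raised (Kera, 0.53; 5 adjusted over the list alone; adjusted p = 0.0037, and adjusted p = 0.648 with an estimated correlation). Over 95 markers of other cells 2 rose, none fell and the median was 0.015. In the stress and translation lists Akt1 (1.49), Sesn1 (1.24) and the secreted stress protein Stc2 (2.81) rose. The glucocorticoid-induced chaperone Fkbp5 fell by 1.75. DESeq2 called 961 genes. Leaving out control Ctr_11734, knockout mKO_11722 or control Ctr_11735 left 395, 396 or 398 genes. The calls of ribosomal proteins (adjusted p = 0.198 without knockout mKO_11721), fast-fibre genes (adjusted p = 0.110 without control Ctr_11745) and fatty acid oxidation (adjusted p = 0.890 without control Ctr_11745) were lost. Those of Myoz2 and Tnni1 were lost in several left-out libraries.

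Ribosome footprints measure which transcripts are being translated in the HA-tagged ribosomes of the same RiboTag animals. Several genes raised in mRNA were raised here too. Spns3 went from 4.66 to 80.8 CPM and Chrna9 from 4.74 to 76.4, with knockout mKO_11688 and control Ctr_11745 far above their groups. Similar rises were those of Cited1 from 10.01 to 123.9, Sln from 10.7 to 83.4, Stum from 4.09 to 39.2 (with control Ctr_11673 far above the other controls) and Vdr from 2.19 to 18.5. Socs2 rose by 1.79 (SE 0.236, adjusted p = 5.25e-04), Eif4ebp1 by 1.07 (SE 0.136, adjusted p = 4.03e-04), Fbxo32 by 0.53 (adjusted p = 0.00677) and Mstn by 0.40 (adjusted p = 0.0218). Igf1 fell by 1.66 (SE 0.149, adjusted p = 3.23e-05). Among lowered genes, Hmga2-ps1 went from 17.9 to 1.92 CPM, Vaultrc5 from 38.0 to 4.56 (with control Ctr_11745 far below the other controls), the class I gene H2-Q4 from 9.07 to 1.24 and Odf3l2 from 24.96 to 3.84. By their names Hmga2-ps1 is a pseudogene and Vaultrc5 a noncoding RNA, so their tags need not come from translation. Trim63 rose by 0.26 (adjusted p = 0.0467) with a call lost in most left-out libraries. The Mstn call was lost without knockout mKO_11688 or control Ctr_11734. Cish (-0.72) and Ddit4 (-0.55) did not pass, although Cish passed without control Ctr_11745 and Ddit4 without control Ctr_11673. In edgeR 3446 of 12979 genes passed, 1412 raised and 2034 lowered (2015 and 2072 with a spread from all 16 libraries), with 2293 called without knockout mKO_11721. Of the tested genes 26.2% had groups without overlap where chance gives 2.86%.

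Most marker lists of cells other than muscle fibres fell in footprints as groups. Those of satellite, erythroid, lymphocyte and skin cells were not called. All 12 fibroblast markers fell (12 adjusted over the list alone; median -0.97, adjusted p = 6.9e-08). So did 13 of 14 macrophage markers (14 adjusted over the list alone; median -1.30, adjusted p = 1.1e-09) and 13 of 14 endothelial markers (13 adjusted over the list alone; median -1.46, adjusted p = 1.3e-07). Further falls were those of 7 of 9 smooth muscle markers (7 adjusted over the list alone; median -1.01, adjusted p = 0.00032) and 7 of 9 tendon markers (7 adjusted over the list alone; median -0.997, adjusted p = 0.0031). For these 5 lists the values ran from adjusted p = 0.294 to adjusted p = 0.388 with an estimated correlation. Examples were the fibroblast genes Col15a1 (-1.79) and Dcn (-0.90), the macrophage genes Ptprc (-1.36) and C1qb (-1.25), and the endothelial genes Flt1 (-1.54) and Kdr (-1.40). Adipocyte markers (5 of 8 lowered; 1 raised and 5 lowered adjusted over the list alone; adjusted p = 0.018; Adipoq at -1.23) and Schwann cell markers (3 of 5 lowered; 4 adjusted over the list alone; adjusted p = 0.030) had adjusted p = 0.388 and adjusted p = 0.401 with an estimated correlation. Matrix genes fell with them, 24 of 29 lowered and 2 raised (25 and 2 adjusted over the list alone; adjusted p = 9.9e-11), including Col3a1 (-1.25) and Col4a1 (-1.39). So did interferon and NF-kB genes, 21 of 30 lowered and 1 raised (23 and 1 adjusted over the list alone; camera adjusted p = 4.3e-07), including B2m (-0.89) and H2-K1 (-1.16). Lipid synthesis genes fell too, 9 of 24 lowered and 1 raised (11 and 1 adjusted over the list alone; adjusted p = 0.0044), including Fads2 (-1.62). For these 3 lists the adjusted p = 0.294 with an estimated correlation. Over all 85 markers of other cells tested in footprints 64 fell and 1 rose, with a median of -1.08 (quartiles -1.33 and -0.68). Over the 95 markers tested in mRNA the median was 0.015.

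**Figure D2:**
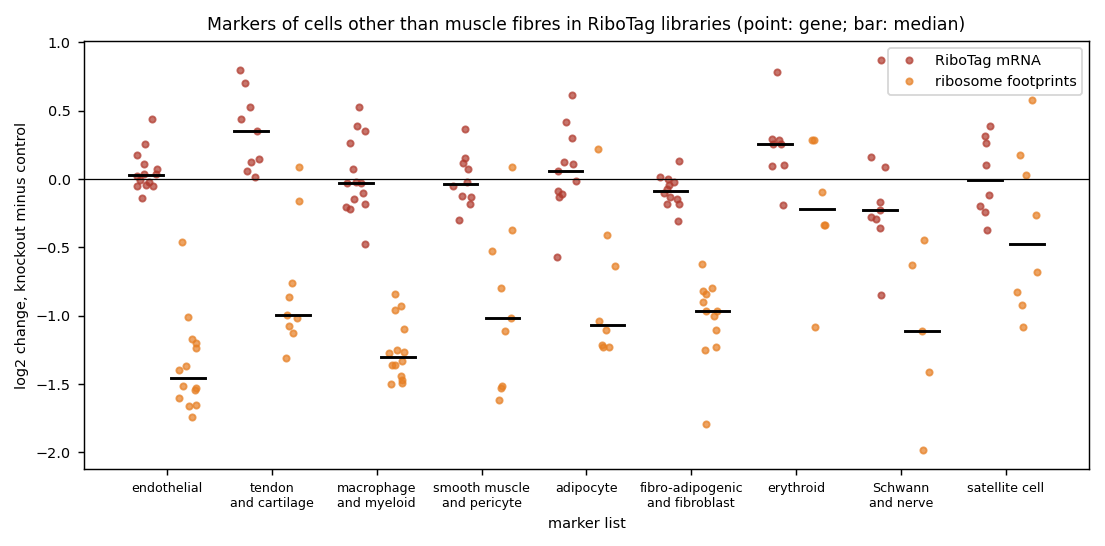
Log2 change, knockout minus control (vertical axis), of each marker gene of 9 cell types other than muscle fibres (horizontal axis) in RiboTag mRNA and in ribosome footprints, with a bar at the median of each list. Footprint points lie mostly below 0 (median -1.08 over 85 markers), and mRNA points lie around 0 (median 0.015 over 95 markers).

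Muscle gene groups also shifted in footprints while the other-cell markers fell. Of 28 glycolysis and glycogen genes 12 fell and 1 rose (17 and 1 adjusted over the list alone; adjusted p = 0.00028, and adjusted p = 0.294 with an estimated correlation), with Phka1 (-0.64) and Pgam2 (-0.43) lower and Fbp2 (1.11) higher. Of 19 fast-fibre genes 7 fell (8 adjusted over the list alone; adjusted p = 0.0075, and adjusted p = 0.403 with an estimated correlation), among them the fast myosins Myh4 (-0.47) and Myh1 (-0.41). Of 16 slow-fibre genes 4 rose (4 adjusted over the list alone; adjusted p = 0.0086, and adjusted p = 0.401 with an estimated correlation), among them Casq2 (1.13) and Myl2 (0.60). Of 27 atrophy and FOXO genes 7 rose (7 adjusted over the list alone), including Foxo3 (0.68) and Foxo4 (0.998), and of 22 denervation genes 7 rose (7 raised and 1 lowered adjusted over the list alone). Of 36 mTORC1 and translation control genes 8 rose and 4 fell (8 and 4 adjusted over the list alone), with Mknk2 at 0.89 and Sesn1 at 0.82. These 3 lists had adjusted p = 0.016, adjusted p = 0.0036 and adjusted p = 0.030. Each had an adjusted p = 0.294 with an estimated correlation. Immediate early genes (4 of 16 raised; 5 adjusted over the list alone; adjusted p = 0.021; Fos at 1.87) and oxidative phosphorylation genes (4 of 71 lowered; 1 adjusted over the list alone; adjusted p = 0.011) had adjusted p = 0.295 and adjusted p = 0.569 with an estimated correlation. The calls of mTORC1 and adipocyte genes were lost without control Ctr_11745 (adjusted p = 0.0906 for each), and that of immediate early genes without control Ctr_11673 (adjusted p = 0.0948). That of oxidative phosphorylation was lost without knockout mKO_11718, knockout mKO_11722 or control Ctr_11745 (highest adjusted p = 0.154), and that of Schwann cell markers without any of 4 libraries (highest adjusted p = 0.104).

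Translation efficiency, the change of footprints beyond that of mRNA, asks which transcripts gain or lose ribosomes for their level. Igf1 lost footprints relative to its mRNA (log2 change -0.97, SE 0.203, adjusted p = 0.00937), and so did Bcl6 (-1.22, SE 0.365, adjusted p = 0.0410). Both lie within the quartiles of the change over 96 markers of other cells (-1.45 and -0.66, median -1.07), from which they were not separated. Socs2 (0.14), Eif4ebp1 (-0.13), Mstn (-0.30), Fbxo32 (0.17), Trim63 (0.31), Cish (-0.45) and Ddit4 (-0.18) did not pass. The largest rises were those of the linker histone gene Hist1h1d (1.86), Dpp6 (1.69), Foxp3 (1.67) and the DNA polymerase gene Polk (1.62). Falls included the imprinted noncoding RNA Mirg (-3.98), Acoxl (-3.15) and Msx1os (-3.02). The ratio holds only for transcripts that poly(A) libraries capture, and for a noncoding RNA such as Mirg it does not measure translation. In edgeR 1480 of 14935 genes passed, 437 raised and 1043 lowered, and DESeq2 called 870 raised and 1272 lowered. A paired fit with animal number as replicate block called 1717. The count was 310 without control Ctr_11734, 373 without knockout mKO_11722, 408 without knockout mKO_11721, 551 without control Ctr_11735, 571 without knockout mKO_11688 and 982 without control Ctr_11673. Of 74 named genes 44, Bcl6 among them, lost their call with at least 1 animal left out.

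Groups lowered in translation efficiency were mostly those of other cells. Of 29 matrix genes 19 fell and none rose (24 and 0 adjusted over the list alone; adjusted p = 9.5e-15), with Col4a1 at -1.14 and Col6a1 at -1.21. Of 14 endothelial markers 12 fell (13 adjusted over the list alone; adjusted p = 3.9e-11), with Tek at -1.65 and Esam at -1.49, and of 9 tendon markers 7 fell (7 adjusted over the list alone; adjusted p = 8.2e-06), with Tnmd at -1.44. Smooth muscle (6 of 10 lowered; 7 adjusted over the list alone; adjusted p = 1.1e-05; Pdgfrb at -1.64) and interferon and NF-kB genes (13 of 34 lowered; 17 adjusted over the list alone; adjusted p = 1.2e-08; Oasl2 at -1.89) followed. These 5 lists each had an adjusted p = 0.205 with an estimated correlation. Fibroblast (4 of 12 lowered; 9 adjusted over the list alone; Dcn at -0.81) and macrophage markers (5 of 14 lowered; 12 adjusted over the list alone; Ptprc at -1.70) both had adjusted p = 6.2e-07. They had adjusted p = 0.248 and adjusted p = 0.286 with an estimated correlation. Over 96 markers of other cells 37 fell and none rose, with a median of -1.07.

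Beside that fall of other-cell markers, some general groups shifted. Of 27 atrophy and FOXO genes 3 rose (3 adjusted over the list alone; adjusted p = 0.00043, and adjusted p = 0.248 with an estimated correlation), namely Foxo4 (0.97), Traf6 (0.85) and Stub1 (0.51). Of 24 lipid synthesis genes 5 fell (5 adjusted over the list alone; adjusted p = 0.0026, and adjusted p = 0.238 with an estimated correlation), including Fads2 (-1.78). Of 24 BCL6 targets reported in other cells 5 fell (6 adjusted over the list alone; adjusted p = 0.0028, and adjusted p = 0.205 with an estimated correlation), including Vcam1 (-1.14) and Ccnd2 (-1.22). Of 75 ribosomal protein genes 5 fell (5 adjusted over the list alone; adjusted p = 0.026, and adjusted p = 0.449 with an estimated correlation), including Rpl6 (-0.90) and Rps6 (-2.65). The helicase gene Eif4a1 of cap-dependent initiation fell by 1.85. Weaker shifts were those of adipocyte (0 of 11; adjusted p = 0.0083) and immediate early genes (1 of 19 lowered, 1 adjusted over the list alone; adjusted p = 0.026). Others were those of oxidative phosphorylation (0 of 72; median 0.12; adjusted p = 0.032), Schwann cell (0 of 9, 2 lowered adjusted over the list alone; adjusted p = 0.044) and erythroid genes (1 of 9 lowered, 1 adjusted over the list alone; adjusted p = 0.048). With an estimated correlation these 5 ran from adjusted p = 0.292 to adjusted p = 0.809. The calls of ribosomal proteins, oxidative phosphorylation, immediate early, erythroid and Schwann cell genes were each lost in at least 1 left-out animal. Examples are adjusted p = 0.122 for ribosomal proteins without control Ctr_11735 and adjusted p = 0.311 for oxidative phosphorylation without control Ctr_11745.

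**Figure D3:**
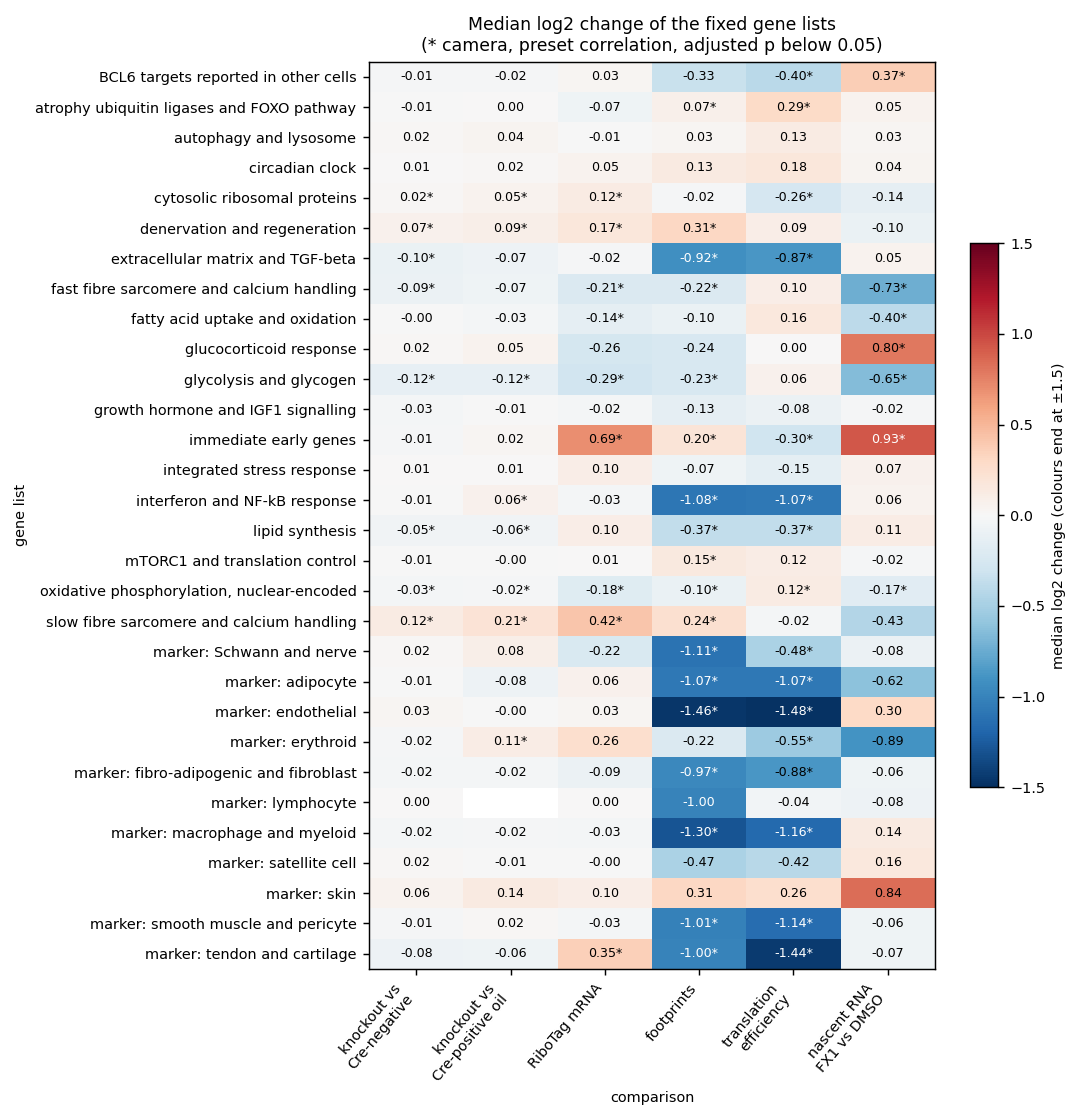
Median log2 change of each fixed gene list (vertical axis) in each of 6 comparisons (horizontal axis), with colours ending at 1.5 and an asterisk for a camera call at the preset correlation. Glycolysis genes are called below 0 in 5 comparisons, from -0.12 to -0.65, but not in translation efficiency (0.06), and fast-fibre genes in 4, from -0.09 to -0.73. With an estimated correlation 0 lists are called in each comparison.

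BCL6 binding was taken from 10925 peaks of 1 library (mm10), of which 52.6% lay in introns, 29.8% between genes and 11.6% in promoters. The peak with the highest score lay in the Socs2 promoter (chromosome 10, 95416796 to 95417016, score 1204). Others of the 10 highest were those at Psmc6 (801), the Cish promoter (715; chromosome 9, 107296574 to 107296794), a Usp46 intron (658), Gm29684 (628), Tnc (606), Arid3b (606), the 5' untranslated region of Bcl6 itself (593; chromosome 16, 23988479 to 23988699), Snx14 (561) and Ctr9 (545). Ddit4 (289), Mstn (180), Eif4ebp1 (132), Vdr (115) and Igf1 (47.8) had peaks assigned to them as well. Genes with a peak within 1 kb of their start were more frequent among raised than among unchanged genes in mRNA: 19.04% against 9.86% versus Cre-negative muscle (odds ratio 2.15), 17.3% against 9.72% versus oil (1.95) and 23.7% against 10.2% in RiboTag mRNA (2.72), with adjusted p = 1.0e-13, adjusted p = 8.0e-15 and adjusted p = 4.4e-10 by Fisher's exact test. Among lowered genes the odds ratios were 1.69 and 1.42 in the first pair of comparisons, and both calls were lost when genes were matched on expression (1.201 and 1.03). In RiboTag mRNA 1.12 did not pass (adjusted p = 0.565), but 1.87 with peaks within 10 kb did. In nascent RNA with FX1 raised genes did not pass (10% against 9.31%, odds ratio 1.08, adjusted p = 0.442; 1.33 with peaks within 10 kb, which passed), and lowered genes were bound more often (12.9%, odds ratio 1.44, adjusted p = 1.6e-05). Genes raised in footprints were bound more often (16.9% against 11.1%, odds ratio 1.62, adjusted p = 3.6e-09). Genes lowered in footprints and in translation efficiency were bound less often than unchanged ones (6.83% against 11.1%, odds ratio 0.585, and 6.33% against 10.5%, odds ratio 0.574). The genes lowered in footprints include 64 of 85 markers of other cells, 6 of the 9 marker lists hold no bound gene, and the share was not separated from that fall. Genes raised in translation efficiency did not pass (1.07).

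H3K27ac after acute and chronic knockout asks where chromatin activity changes without BCL6 and whether this is at its binding sites (the column headers mark the series 1w and 12w). Controls of all H3K27ac series were Cre-negative, so loss of BCL6 and presence of the Cre transgene cannot be told apart in them. In the acute series 67 of 67976 regions passed in limma, 64 raised and 3 lowered. A region in a Usp46 intron (chromosome 5, 74020285 to 74020785) that holds the BCL6 peak with score 658 went from 0.477 ± 0.434 to 22.1 ± 7.53 scaled tags (tags per 10000000; SD, n = 3 each; adjusted p = 0.00265). The Chrna9 promoter (chromosome 5, 65966425 to 65966925) went from 0.627 to 17.5 (adjusted p = 0.0253), the Cyp2j11 promoter (chromosome 4, 96348765 to 96349265) from 1.34 to 23.2 (adjusted p = 0.00178), and an intron of Vdr (chromosome 15, 97878639 to 97879139) from 1.69 to 22.6 (adjusted p = 0.00393). An exon of Esr1 (chromosome 10, 4856769 to 4857269) went from 2.24 ± 1.82 to 38.6 ± 4.03 (SD, n = 3 each; adjusted p = 2.17e-05), while the other 10 Esr1 regions had changes from -0.53 to 0.96 and did not pass. The lowered regions were assigned to Serpini2 (-2.06), Ppp1cc (-1.58) and Gm19689 (-1.35). Of the 64 raised regions 25 overlapped a BCL6 peak (39.1%, against 5.0% of all regions; odds ratio 12.3). The median change was 0.084 in overlapping and 0.0012 in other regions (camera p = 3.4e-04, and p = 0.128 with an estimated correlation). The count was 18 without knockout imKO_6346, 20 without knockout imKO_6349 and 36 without Cre-negative Ctr_6366. The edgeR fit on recovered reads called 177 regions, and all 8 named called regions lost their call in at least 1 alternative.

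In the chronic series 120 of 65836 regions passed, 112 raised and 8 lowered. The Esr1 exon region was again among the largest rises (from 1.00 ± 1.38 to 35.4 ± 3.85 scaled tags, SD, n = 3 each; adjusted p = 0.0037), with regions assigned to Ctnnbl1 (4.33), Gm14858 (4.06), Zfp777 (4.03) and the growth factor gene Pdgfc (4.02). An intron region of Eif4ebp1 (chromosome 8, 27262406 to 27263383) rose by 1.89, from 17.2 to 64.0 scaled tags (adjusted p = 0.010). Further, 2 regions downstream of Cish (chromosome 9, 107305317 to 107305817 and 107307320 to 107307820) rose by 1.74 and 1.99. Lowered regions included those assigned to Aldh8a1 (-2.68), Sorl1 (-2.50) and Vldlr (-1.92). Of the raised regions 47 overlapped a BCL6 peak (42.0%, against 5.13% of all regions; odds ratio 13.5). The median change was 0.135 in overlapping and 0.034 in other regions (camera p = 5.5e-06, and p = 0.155 with an estimated correlation). With distal and promoter regions taken apart, the difference of medians was 0.149 and 0.044, and in the acute series 0.123 and 0.016. The count was 0 without knockout imKO_1802, 1 without knockout imKO_1794, 6 without knockout imKO_1803 and 409 without Cre-negative Ctr_1801, which had the fewest tags. The edgeR fit on recovered reads with TMM called 387 regions. Across 63901 regions the acute and chronic changes had a Pearson correlation of 0.168, and 33 regions were raised in both (0.108 if independent).

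**Figure D4:**
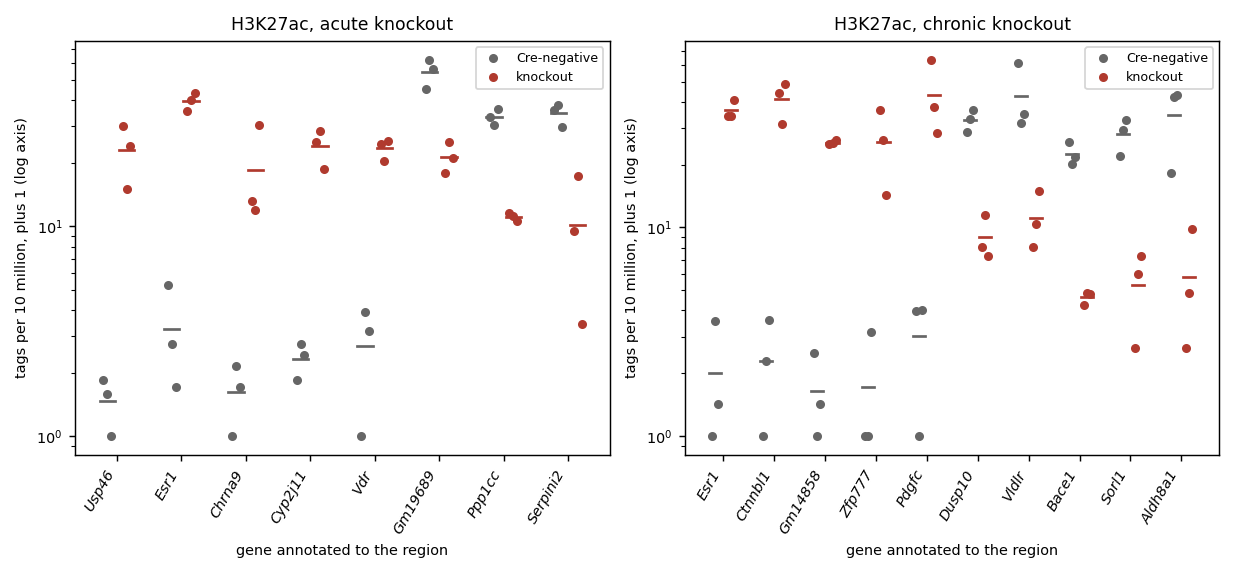
H3K27ac signal per library (scaled tags plus 1, log axis) in the called regions with the largest changes, by the gene annotated to them (horizontal axis), for acute and chronic knockouts and Cre-negative controls, with a line at each mean of 3 libraries. The Esr1 exon region has knockout means of 38.6 and 35.4 against 2.24 and 1.00 in controls.

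In animals that also had RNA sequencing, H3K27ac was counted in 1 kb windows on BCL6 peaks. Most windows that changed were raised: 1654 of 9167 passed, 1522 raised and 132 lowered. The excess was smaller with edgeR and TMM on recovered reads (1009 raised, 380 lowered) and with quantile normalization (875 raised, 522 lowered). The windows took 7.45% to 8.14% of the tags in knockouts and 6.39% to 6.97% in controls. The Socs2 promoter window (chromosome 10, 95416406 to 95417406) rose by 1.22 (adjusted p = 2.5e-05), from 161.5 to 374.6 scaled tags. Windows of Eif4ebp1 rose by 0.74, 1.46 and 1.52, a Ddit4 window by 1.2 and 2 overlapping Fbxo32 promoter windows by 0.53 each. The largest rises were at Usp46 (4.65), Cyp2j11 (4.60), 1700012D16Rik (4.57), Ypel5 (4.04) and Ctnnbl1 (3.86). An Igf1 window fell by 1.05, and the largest falls were at Odf3l1 (-2.79), Afap1 (-2.56), Rnf216 (-2.28), Twist2 (-1.97) and Gm36738 (-1.94). Windows within 1 kb of a transcription start had a median change of 0.087 and those farther away 0.167. The median was 0.192 in windows of higher and 0.079 in windows of lower peak score. Scaling to library totals set the median of all windows at 0.137, against -0.02 with TMM and -0.07 with quantile normalization. The rises of Cish (0.85) and Bcl6 (1.16 and 0.27) windows were not called with edgeR and TMM. DESeq2 called 1029 windows, and the count was 1045 without knockout mKO_1900 and 1068 without knockout mKO_1907. For 1490 genes with a promoter window, the RNA change against Cre-negative muscle and the acetylation change had a Pearson correlation of 0.352 and a Spearman correlation of 0.256 across genes. Some animals are in both, and the value expected without a knockout effect was not computed. Of 158 genes with raised RNA 58 had a raised window, and of 195 genes with lowered RNA 3 had a lowered window, where 121 windows of the 1490 genes were raised and 4 lowered. With edgeR and TMM, 46 of these windows were raised and 43 lowered, 33 of them raised with raised RNA and 22 lowered with lowered RNA. The median acetylation change was 0.265 for raised, 0.056 for lowered and 0.080 for unchanged RNA, and 0.10, -0.11 and -0.09 with TMM.

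**Figure D5:**
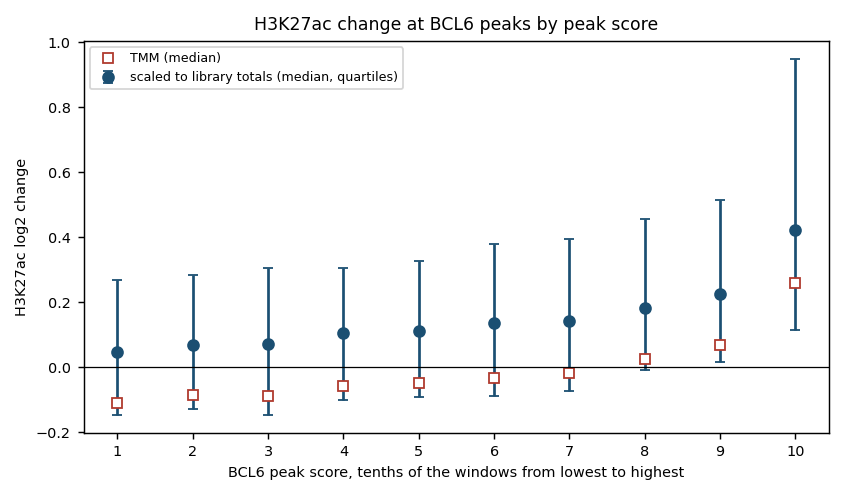
Median log2 change of H3K27ac (vertical axis, with quartiles) in BCL6 peak windows in 10 groups by BCL6 peak score from low to high (horizontal axis), for values scaled to library totals and for TMM. The median goes from 0.047 in the lowest to 0.423 in the highest group, and with TMM from -0.11 to 0.26.

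Nascent RNA in wild-type mice given FX1 or DMSO asks what an inhibitor of BCL6 does to transcription in muscle. Cish transcription fell by 2.03 (SE 0.293, adjusted p = 9.9e-04) and that of Igf1 by 1.24 (SE 0.254, adjusted p = 0.00609), from 10.02 ± 0.50 to 8.78 ± 0.43 (SD, n = 5 each). Eif4ebp1 rose by 1.09 (SE 0.233, adjusted p = 0.0074), Trim63 by 1.31 (SE 0.284, adjusted p = 0.00805) and Ddit4 by 2.38 (SE 0.299, adjusted p = 4.46e-04). Fbxo32 fell by 0.72 (adjusted p = 0.0435), a call lost in most left-out libraries. Socs2 (0.65, adjusted p = 0.122) and Mstn (0.22) did not pass. Socs2 passed without FX1 sample 3, which stood far below the other FX1 samples. The largest rises were those of Arl4d (3.16), Adamtsl2 (3.08), the serine protease gene Htra1 (2.96), the transcription factor gene Maff (2.91), Apold1 (2.88) and Hopx (2.69). The largest falls were those of Tmem233 (-2.91), the urocortin receptor gene Crhr2 (-2.66), H60b (-2.51, with FX1 sample 3 far above the other FX1 samples), the AMP deaminase gene Ampd1 (-2.40), Sec14l5 (-2.36, with DMSO sample 4 far above the others) and Tekt1 (-2.24). In limma 3229 of 15683 genes passed, 1640 raised and 1589 lowered, with 16.5% of genes without overlap where chance gives 0.794%.

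Glucocorticoid response genes rose with FX1, with 11 of 17 raised and none lowered (12 and 0 adjusted over the list alone; adjusted p = 8.1e-07, and adjusted p = 0.763 with an estimated correlation), among them Fkbp5 (2.002), Errfi1 (2.49) and Lcn2 (2.57). Of 18 immediate early genes 8 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 0.00055, and adjusted p = 0.925 with an estimated correlation), with the RNA decay factor Zfp36 at 2.34 and Fosl2 at 1.58. Of 19 fast-fibre genes 10 fell (11 adjusted over the list alone; adjusted p = 4.9e-06, and adjusted p = 0.763 with an estimated correlation), including parvalbumin (Pvalb, -1.13) and Casq1 (-1.19). Of 28 glycolysis and glycogen genes 15 fell and 1 rose (16 and 1 adjusted over the list alone; adjusted p = 0.00015), with Tpi1 (-1.06) and Pgam2 (-0.87) lower and Pgm1 (1.28) higher. Of 35 fatty acid oxidation genes 15 fell and 4 rose (18 and 4 adjusted over the list alone; adjusted p = 5.9e-04), with Cpt1b at -1.22 and Acadm at -1.04. Both had an adjusted p = 0.853 with an estimated correlation. Of 72 oxidative phosphorylation genes 6 fell (0 adjusted over the list alone; median -0.17, adjusted p = 0.0069, and adjusted p = 0.993 with an estimated correlation). Of 23 BCL6 targets reported in other cells 6 rose and 1 fell (6 and 2 adjusted over the list alone; adjusted p = 0.042, and adjusted p = 0.925 with an estimated correlation), with the survival gene Bcl2l1 at 1.77 and the cell cycle inhibitor Cdkn1a at 2.11. Slow-fibre genes, raised as a list in RNA and footprints of knockouts, were not called as a list with FX1. Over 85 markers of other cells 11 rose and 10 fell. A fit with the sample number as replicate block called 1853 genes, though the numbers did not pair the samples. The calls of oxidative phosphorylation and BCL6 target genes were lost without FX1 1, FX1 5 or DMSO 1 and, for the targets, DMSO 4 (highest adjusted p = 0.107 and adjusted p = 0.103).

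Changes were then compared across assays, gene by gene, where genes are not independent replicates. Knockout against Cre-negative muscle and RiboTag mRNA, which share no animals, had a Pearson correlation of 0.476 across 13575 genes, with 175 genes raised in both (15.8 if independent) and 222 lowered in both (29.3 if independent). RiboTag mRNA and footprints had a correlation of 0.332 across 12438 genes, but they come from the same 8 animals, and 9 of the 35 splits of these animals gave a correlation as large, the real split included (highest other 0.497). In the 18 splits with 2 knockouts in each group it ran from 0.041 to 0.360. Called in both were 170 raised and 179 lowered genes. Knockout against Cre-negative muscle and nascent RNA with FX1 had a correlation of 0.063 across 13124 genes. Raised in both were 92 genes (88.0 if independent) and lowered in both 261 (126 if independent). In opposite directions 223 changed, a count for which the number if independent was not computed, so it is not read as discordance.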

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

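The tests of explanations, the counts over other splits of the libraries and the test of chronic against acute H3K27ac were chosen only after the results were seen.

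Markers of cells other than muscle fibres were lower in knockout footprints but not in mRNA of the same animals, a pattern that weighs on every matrix, vessel and immune gene lowered there. The falls of Igf1 and Bcl6 in translation efficiency are of like size and were not separated from this pattern. A single common fall over all 9 marker lists, as from less carry-over of untagged ribosomes in the knockout pull-downs, stays open: the lists differed as much in 6 of the 35 splits of the animals, the real split included (sum of squares of log2 differences 0.899, highest other 2.07). A single unusual animal was argued against, since the median over markers stayed at -0.88 or lower with any animal left out. Lower translation in those cells could give the same values, as their median mRNA change was 0.015, and this cannot be told apart from smaller carry-over. The labels list the anti-HA antibody for the mRNA libraries too, so whether they hold RNA of whole muscle or of the pull-down is open. Footprints from sorted cells or from the input of the pull-down would separate these.

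Esr1 RNA and acetylation of a single Esr1 exon were higher in knockout than in Cre-negative muscle. Sequence of the Cre transgene, which carries part of the estrogen receptor, may be counted as Esr1, and this fits the change of 0.016 against oil controls that carry the same transgene. Higher transcription of Esr1 itself was argued against by the change of -0.011 in RiboTag mRNA, where both groups carry Cre. Reads over the junction of Cre and Esr1 would settle it.

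Most of the called H3K27ac windows on BCL6 peaks were raised in knockout muscle. Scaling, or a gain shared alike by all windows, as the whole cause was argued against, since edgeR with TMM still called 1009 windows raised against 380 lowered, and quantile normalization 875 against 522, though the excess was smaller. A gain that depends on the signal of a window, as from a more efficient pull-down, predicts no correlation with peak score within groups of like signal. The lowest was 0.175 (Spearman), but another split of the libraries gave a median of 0.191 in size, so this gain stays open. Acetylation gained in proportion to BCL6 binding fits the median correlation of 0.242, against 0.191 at most in the 9 other splits, which are too few for a share under 0.05. A suggested test is binding and acetylation in the same animals with spike-in chromatin.

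Over splits of the libraries between the groups, the real split is included in each count. For genes, only 1 split reached the real count in each of 6 comparisons: of 100 against Cre-negative muscle (2096 genes, highest other 409), against oil (3216, highest other 745) and in nascent RNA (3229, highest other 937), and of 35 in RiboTag mRNA (609, highest other 1), footprints (3446, highest other 16) and translation efficiency (1480, highest other 325). For gene lists, 38 of 100 splits reached the real count against Cre-negative muscle (8 lists, highest other 17), 39 of 100 against oil (8, highest other 15), 24 of 35 in RiboTag mRNA (9, highest other 18), 1 of 35 in footprints (18, highest other 15), 3 of 35 in translation efficiency (16, highest other 18) and 65 of 100 in nascent RNA (7, highest other 17). Why other splits reach the list counts was not tested: in RiboTag mRNA they gave 1 gene at most but up to 18 lists, and a preset correlation too low for these lists could give this, as could structure among the samples. For the correlation of RiboTag mRNA with footprint changes, 9 of 35 splits reached the real value (0.332, highest other 0.497), so chance is not excluded. The H3K27ac comparisons have 10 splits, too few for a share under 0.05: 67 regions against 10 at most in the acute series, 120 against 0 in the chronic series and 1654 against 0 in windows, each with 1 split as large, and for the difference at BCL6 peaks 0.083 against 0.083 (2 splits as large) and 0.1004 against 0.088 (1 split as large).

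In 225 groups tested for a library far from the rest, 17 had such a library (7.56%), and about 1 in 20 is flagged by chance. The ratio given is the gap to the next library over the range of the group. Socs2 was high in knockout P1900 in the fits against Cre-negative muscle (0.727) and oil (0.723). Esr1 was low in Cre-negative P1898 (0.846), Fbxo32 high in Cre-negative P1909 (0.945) and Ddit4 high in oil P1910 (0.872). In RiboTag knockout mKO_11688, Chrna9 was high in mRNA (0.927) and footprints (0.889) and Igf1 high in mRNA (0.890). In control footprints, Chrna9 was high in Ctr_11745 (0.835), Stum high in Ctr_11673 (0.854) and Vaultrc5 low in Ctr_11745 (0.919). In nascent RNA, H60b was high (0.847) and Socs2 low (0.822) in FX1 3, and Sec14l5 was high in DMSO 4 (0.884). Among library measures, total tags were low in RiboTag control mRNA Ctr_11745 (0.920), and the mean correlation with the group was low in DMSO 4 (0.871) and in knockout footprints mKO_11718 (0.901).

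Chronic and acute H3K27ac changes differed in 4 of 71875 regions by edgeR (3727 with unadjusted p below the threshold) and in 0 by limma (3700 with unadjusted p below it). The difference was -1.87 at Tekt1 (chromosome 11, 72369603 to 72370273), 2.15 at Cish (chromosome 9, 107307320 to 107307820), 1.71 at Mybph (chromosome 1, 134194464 to 134195394) and 2.31 at Agtr1b (chromosome 3, 20792261 to 20792954).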

How the results depend on the processing

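Quantile normalization, a common variance prior, leaving out genes near the position cap, edgeR with TMM on recovered reads, a pseudocount of 5 and the block in list tests were chosen only after the data were seen; the other alternatives were planned. A direction counts as reversed when the sign of a log2 change, or the majority of called genes, changes side. RLE and DESeq2 on the log2 tables, and a joint fit of the 13 RNA libraries, were not run, because those tables hold no counts and were transformed separately.

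The count against Cre-negative muscle (2096) held, at 1703 to 1916 with a library left out, as did that against oil (3216), at 2589 to 3094; with quantile normalization the raised share went from 39.6% to 48.3% against Cre-negative muscle and turned from 42.3% to 51.0% against oil. In RiboTag mRNA (609) DESeq2 called 961, and left-out libraries gave 395 (without control Ctr_11734) to 826, with 396 without knockout mKO_11722 and 398 without control Ctr_11735; the raised share ran from 41.5% to 51.4%, a majority without knockout mKO_11688. Footprints (3446) ran from 2293 (without knockout mKO_11721) to 3761 with a library left out, and with a spread from all 16 libraries 4087 were called, 2015 raised and 2072 lowered. Translation efficiency (1480) became 2142 with DESeq2, 870 raised and 1272 lowered, and with an animal left out ran from 310 (without control Ctr_11734) to 1892 (without control Ctr_11745), with 373 without knockout mKO_11722, 408 without knockout mKO_11721, 551 without control Ctr_11735, 571 without knockout mKO_11688 and 982 without control Ctr_11673, and the paired fit with animal number as replicate block called 1717. For these 3 results the cause was not tested.

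Where edgeR on recovered reads replaced limma, acute H3K27ac regions (67) became 177 with TMM, 170 with RLE and 172 with library totals, and chronic regions (120) became 387, 383 and 279; fit and scaling changed together with TMM and RLE, and the fit with library totals. Acute regions became 145 with a pseudocount of 5, and 18 (without knockout imKO_6346) to 83 (without knockout imKO_6348), with 20 without knockout imKO_6349 and 36 without Cre-negative Ctr_6366. Chronic regions became 323 with DESeq2 on recovered reads, 70 with the stricter filter, 240 with a pseudocount of 5 and 305 with quantile normalization, and 0 (without knockout imKO_1802) to 409 (without Cre-negative Ctr_1801), with 1 without knockout imKO_1794 and 6 without knockout imKO_1803. Windows (1654) became 1029 with DESeq2, and 1045 (without knockout mKO_1900) to 1650, with 1068 without knockout mKO_1907. For these 3 counts the cause was not tested. The difference of medians at BCL6 peaks kept its sign in both alternatives, which only redefined the peaks and kept the preset correlation. With peak centres within the region it was 0.084 (acute) and 0.097 (chronic), and with peaks of higher score 0.116 and 0.148. In the main setting it did not pass with an estimated correlation in either series. By fry it did not pass there for a shift in a common direction, but did for changes in mixed directions.

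Nascent RNA (3229) became 1853 with the sample number as replicate block, and 2192 (without DMSO 3) to 4561 (without FX1 3). Its raised share turned to 49.7% without the filter and 47.6% with quantile normalization, and ran from 48.5% (without DMSO 1) to 51.8% with a library left out; the cause was not tested.

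The bound share of lowered genes was weaker against Cre-negative muscle when matched on expression (odds ratio 1.201), and against oil with peaks of higher score (1.23) or matched on expression (1.03). With peaks within 10 kb it was stronger for genes lowered in RiboTag mRNA (1.87) and raised in nascent RNA (1.33). For these results the cause was not tested.

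With an estimated correlation 0 lists were called in each of 6 comparisons (8, 8, 9, 18, 16 and 7 with the preset), and fry called 1 in RiboTag mRNA. Left-out libraries gave 5 (without DMSO 1) to 11 (without FX1 3) lists in nascent RNA and 7 to 13 in RiboTag mRNA; the cause was not tested.

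Correlations were also taken over well-expressed features only and over called features only. They became 0.595 and 0.646 for Cre-negative muscle with RiboTag mRNA, 0.099 and 0.090 with nascent RNA, and 0.866 and 0.898 with oil. For RiboTag mRNA with footprints they became 0.386 and 0.447, and for acute with chronic regions 0.203 and 0.626. Called features are those called in either comparison of a pair. They were chosen on the changes being correlated, which can by itself raise the correlation, so these values do not measure robustness. For the well-expressed features the cause was not tested.

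With quantile normalization Atp5a1 turned to 0.021 against Cre-negative muscle and Lpl to 0.0064 against oil. Named genes with the same call in all alternatives were 54 of 70 against Cre-negative muscle, 70 of 84 against oil, 40 of 50 in RiboTag mRNA, 82 of 97 in footprints, 30 of 74 in translation efficiency and 73 of 91 in nascent RNA, and named regions 0 of 8 acute, 0 of 13 chronic and 18 of 23 windows.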

Other observations

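No test in this part was chosen only after the result was seen, except the counts over marker genes of other cells and over genes near the position cap.

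Several lists were not called in any comparison. Of 30 autophagy and lysosome genes 4 rose and 2 fell against Cre-negative muscle (adjusted p = 0.369), and of 19 circadian clock genes 2 rose in translation efficiency (adjusted p = 0.0517), Arntl (0.92) among them, while in nascent RNA 4 rose and 4 fell (adjusted p = 0.943), with Dbp (-1.38) and Nr1d1 (-1.32) lower. Integrated stress response genes included lowered Asns (-2.09) and Aldh18a1 (-0.86) in translation efficiency, 3 lowered and none raised (adjusted p = 0.0518). Of 26 growth hormone and IGF1 genes 3 rose and 6 fell in nascent RNA (adjusted p = 0.561), including Irs1 (-1.18). Of 8 satellite cell markers 1 rose and 3 fell in footprints (adjusted p = 0.227), of 2 tested lymphocyte markers 1 fell there (adjusted p = 0.0556), and of 2 tested skin markers 1 rose (adjusted p = 0.276).

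In the authors' deposited tables, 1623 genes passed against Cre-negative muscle (1578 also called here), 2366 against oil (2302), 4240 in nascent RNA (3199) and 3090 in translation efficiency (1297). The authors' deposited table gives Igf1 at -1.31 and Chrna9 at 1.32 against Cre-negative muscle, and Chrna9 at 4.09 against oil, and in translation efficiency Igf1 at -1.41 and Bcl6 at -1.68.

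Genes taken here as those of other cells were abundant in the footprints of both groups. Gsn stood at 613.5 CPM in knockout and 1172 CPM in control footprints, Thbs4 at 395.6 and 701.5, and Dcn at 292.3 and 532.5. Whether muscle fibres express them too was not tested, so these values do not measure carry-over. Genes near the position cap made up 84 of the called genes in RiboTag mRNA, 304 in footprints and 100 in translation efficiency.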
